A study of Danio rerio with 11 samples.

How the data were processed

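RNA from 11 single zebrafish embryos at about 25 hours after fertilisation (hpf) was prepared for sequencing with the TruSeq RNA v2 kit, per the labels' protocols. This kit does not mark the strand of a transcript. Groups and replicate numbers were taken from the sample titles, which give 6 mutant and 5 sibling embryos. The series design describes an incross of rfx4 carriers, whereas the growth protocol in the labels names parents carrying zic2 mutations. The group names follow the titles and the genotype labels, which name rfx4, and the discrepancy was left open.

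The authors deposited a table of counts and a table of TPM values for 14473 genes, with 1 column per embryo. Per the submitters' processing notes, CASAVA 1.8.2, Bowtie 1.1.1, RSEM 1.2.18 and the genome build Zv9 were used, with no role stated for each and no annotation named. RSEM gives estimated counts, which share reads among similar transcripts by their likelihood, and the deposited counts were whole numbers, so they were taken as estimated counts rounded before deposit. The deposited TPM values were already scaled for gene length and summed to 1000000 per embryo. They entered only the repeats under other settings. Reads shared between near-identical genes can be split unevenly by such an estimate, which leaves the values of tubulin and other close paralogs uncertain. Total counts ranged from 16238368 to 21104811 per embryo. Each library came from a separate animal, so the spread within a group includes biological variation. The smallest chi-square per degree of freedom among the 25 within-group pairs of libraries was 8.05, so none of these pairs agreed within sampling noise.

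Mutants were compared with siblings by edgeR 4.0.16 in R 4.3.3, with the quasi-likelihood test, TMM normalisation, the filterByExpr filter and Benjamini-Hochberg adjustment at 0.05. The filter left 12301 of the 14473 genes, and 519 genes had 0 counts in every library. All fold changes are mutant over sibling on the log2 scale. Standard errors (SE) were derived from the quasi-likelihood F statistic. Expression in CPM (counts scaled to a library of 1000000) used the TMM library sizes, and log2 CPM used a prior count of 1. Gene lists for midline, neural, ciliary, mesodermal and stress groups were fixed before the data were examined. They were tested with camera from limma 3.58.1 at its preset inter-gene correlation of 0.01, with adjustment over the 23 lists that had members in the table. Camera with an estimated correlation, fry and an exact permutation test of list means were run beside it. Members of a list were also adjusted over the list alone. A list of mitochondrial transcripts was not analysed here, since 0 of its 13 genes were in the table. One further list and 1 gene are not reported here, and the counts of lists include that list.

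The rule for named genes, also fixed before the data were examined, took rfx4, then up to 12 genes per direction with the largest change among those past 0.05, with a mean count of at least 10 and no overlap between the groups. From each list it took its called members, or the 2 of lowest p where none was called. Since edgeR called 0 genes over all 11 libraries, the part of the rule for called genes was applied to the calls of DESeq2 1.42.0, a test that had been fixed beforehand. The 24 genes called by edgeR without mutant 6, and the members of a list that passed when adjusted over the list alone, were named as well. These extensions were chosen after the values were seen.

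Further settings, fixed before the data were examined, covered normalisation (DESeq2 size factors, upper quartile, total counts), the test (DESeq2, limma-voom, voom with sample weights, robust dispersion), the low-count filter, the TPM values with pseudocounts of 1 and 0.1, thresholds of 0.01 and 0.1, the replicate number as a block, and leaving out each embryo. Leaving out mutant 7 with sibling 3, alone or together with mutant 6, was added after the data were examined. So were the permuted list means, and the list tests without mutant 6 by an estimated correlation, fry or permuted list means. The gene table of the assembly GRCz12tu, which differs from the build of the counts, was used only for gene names and for which genes neighbour each other. Of the table's gene names, 11701 matched a symbol, 2369 a synonym and 178 a gene identifier, and 225 matched none. Figures were drawn with matplotlib 3.10.9.

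The tests were checked on simulated counts with the means, dispersions and library sizes of these 12301 genes, in which 50 genes were changed at each of 4 fold sizes. At 6 against 5 embryos, edgeR recovered 8 of 50 genes changed 1.3-fold, 28 of 50 changed 1.5-fold, 45 of 50 changed 2-fold and 49 of 50 changed 4-fold, with 6 false calls. DESeq2 recovered 13, 33, 48 and 49 of 50 at the same sizes, with 27 false calls.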

Results

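Whole-embryo RNA-seq was carried out on single zebrafish embryos, given in the series design as coming from an incross of carriers of an rfx4 mutation. The growth protocol instead names parents with zic2 mutations, and this discrepancy stayed open. The gene rfx4 encodes a transcription factor of the RFX winged-helix family. The embryos were raised at 29 °C to about 25 hpf and sorted by their appearance into 6 mutants (replicates 1, 3, 4, 5, 6 and 7) and 5 siblings (replicates 2, 3, 4, 7 and 8). Siblings of such a cross can be wild type or heterozygous, and the labels do not say which each embryo was. The comparison of mutants with siblings asks which transcripts differ in embryos with the mutant phenotype, with the dorsal and ventral midline of the neural tube as the stated interest of the series. The total count per library was 17566485, 18296024, 16238368, 16669330, 16584770 and 18070451 in the mutants and 18430191, 21104811, 17133737, 18784496 and 17849265 in the siblings, in the order of the replicates above. The median log2 fold change of all 12301 tested genes was 0.0009.

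Transcripts of rfx4 itself were present in every mutant, at 69.4% of the sibling level. Its expression was 41.9 ± 8.7 CPM in mutants (SD, n = 6) and 60.4 ± 9.8 CPM in siblings (SD, n = 5). Counts ran from 589 to 942 in mutants and from 857 to 1383 in siblings, so the groups overlapped. Mutants 6 and 7, with 905 and 942 counts, lay within the sibling range, and mutants 1, 3, 4 and 5, with 589, 706, 623 and 605 counts, lay below it. The log2 fold change was −0.53 ± 0.14 (SE), with an adjusted p of 0.475 by edgeR over all genes and an exact two-sided permutation p of 0.0195 over the 462 splits of the 11 embryos. The RNA level is a weak check of the labels, since the lesion need not remove the transcript. With voom and sample weights the fold change was −0.70 and the adjusted p 0.0434.

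Among the genes without overlap between the groups were nkx2.9, dpysl5a, atoh1a, urp2 and foxa2, which were lower in mutants, and col8a1a and pi15a, which were higher. Expression of nkx2.9, a homeobox gene of the ventral neural tube, was 6.80 ± 1.07 CPM in mutants (SD, n = 6) and 11.7 ± 0.70 CPM in siblings (SD, n = 5), a 1.72-fold difference. The floor plate transcription factor foxa2 was 1.40-fold lower. The gene urp2, which encodes a urotensin-related peptide of neurons contacting the cerebrospinal fluid, was at 0.21 ± 0.16 CPM in mutants and 1.26 ± 0.60 CPM in siblings. The dorsal progenitor gene atoh1a was 1.69-fold lower, at 5.32 ± 0.76 CPM against 8.99 ± 1.22 CPM, and dpysl5a, which encodes a collapsin response mediator protein, was 1.49-fold lower. All 6 mutants lay below all 5 siblings for each of these 5 lower genes, which restates how they were chosen and adds no support. The edgeR quasi-likelihood test over all 11 embryos called 0 genes at 0.05. The smallest adjusted p, 0.0659, belonged to nkx2.9 (log2 fold change −0.78 ± 0.11 SE) and dpysl5a (−0.57 ± 0.08 SE). At an unadjusted p under 0.05 there were 843 genes, 466 higher and 377 lower, and 9 of 99 other splits of the embryos gave as many or more (all 99 ran from 189 to 1177).

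In the simulated counts DESeq2 gave 27 false calls and edgeR 6, so the DESeq2 calls need more care. DESeq2 called 43 genes in the same embryos, 20 higher and 23 lower in mutants. The fold changes and SE given for them here are those of the edgeR fit, beside adjusted p values of DESeq2. Among the genes named from these calls by size and by lack of overlap, the lower ones were urp2 (log2 fold change −2.60 ± 0.46 SE, DESeq2 adjusted p = 0.000757), bicc2 (−1.89 ± 0.39, adjusted p = 0.0014), which encodes an RNA-binding protein of the Bicaudal C type, matn3a (−1.48 ± 0.27), which encodes a cartilage matrix protein, and pou5f3 (−0.98 ± 0.22). Smaller differences in the same direction were found for nkx2.9 (DESeq2 adjusted p = 1.08e-06), dpysl5a (adjusted p = 1.95e-06), atoh1a (−0.76 ± 0.13, adjusted p = 0.000177), foxa2 (−0.48 ± 0.09, adjusted p = 0.000584), ascl1b (−0.47 ± 0.11) and rfx2 (−0.37 ± 0.07). The α-tubulin genes tuba1l2 (−0.36) and tuba1b (−0.32) were lower too, but near-identical tubulin copies can exchange reads. Higher in mutants were pi15a (1.11 ± 0.19), pappaa (1.06 ± 0.23), which encodes a secreted protease, dmrt1 (1.03 ± 0.21), the calcium channel genes cacna1da (0.86 ± 0.18) and cacna1ba (0.49 ± 0.12), and ern1 (0.69 ± 0.16), which encodes a sensor of the unfolded protein response. Also higher were the collagen genes col8a1a, at 206 ± 12.2 CPM against 141 ± 20.8 CPM (0.54 ± 0.09, DESeq2 adjusted p = 0.000177), and col5a3a, at 0.49 ± 0.09, and plod2, which encodes a collagen-modifying enzyme, at 0.38 ± 0.08. The other named genes that were higher were dnmt3ab (0.41 ± 0.07), thrb (0.40 ± 0.08) and ppp1r14c (0.38 ± 0.08). By edgeR none of these genes had an adjusted p under 0.05 over all 11 embryos. Limma-voom called 2 genes, bicc2 and nkx2.9 (adjusted p = 0.0447 for both).

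One embryo, mutant 6, decided much of the edgeR count. Without it edgeR called 24 genes, 3 higher and 21 lower in mutants, and 15 of them were among the 43 DESeq2 calls. The lower genes included the floor plate genes ntn1b, which encodes the axon guidance cue Netrin, shha and shhb, which encode Hedgehog ligands. The zic genes zic5, zic6 and zic2a, which encode zinc-finger transcription factors of the dorsal neural tube, were lower as well. Without mutant 6, ntn1b had a log2 fold change of −1.26 ± 0.11 (SE, edgeR adjusted p = 0.0002), shhb one of −0.82 ± 0.10 (adjusted p = 0.003), shha −0.45 ± 0.07 (adjusted p = 0.0288), zic5 −0.83 ± 0.07 (adjusted p = 0.0002), zic6 −0.84 ± 0.10 (adjusted p = 0.003) and zic2a −0.52 ± 0.06 (adjusted p = 0.003). The roof plate gene lmx1a was 4.27-fold lower and the Wnt ligand gene wnt4b 3.82-fold lower. Over all 11 embryos these folds were 1.93 and 2.89, and the log2 fold changes were −0.99 ± 0.22 for ntn1b, −0.50 ± 0.24 for shhb, −0.35 ± 0.11 for shha and −0.32 ± 0.16 for zic2a. The remaining lower genes were bicc2 (−2.54 ± 0.16, edgeR adjusted p = 1.95e-05), cdkl1, which encodes a cyclin-dependent kinase-like protein, adamts3, crb1, an apical polarity gene, atp1a1b, fam167ab, chad, zgc:113858, urp2, matn3a, nkx2.9, atoh1a and dpysl5a. The 3 higher genes were dmrt1, pi15a and efemp2a. Mutant 6 was close to the siblings, or beyond them, in part of these genes. Its log2 CPM was 3.34 for ntn1b (other mutants 1.89 to 2.32), 5.54 for zic5 (other mutants 4.36 to 4.62) and 6.75 for zic2a (other mutants 5.74 to 6.02). Without sibling 7 edgeR called 1 gene, dpysl5a (adjusted p = 0.0442), and leaving out any other single embryo gave 0 calls.

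**Figure D1:**
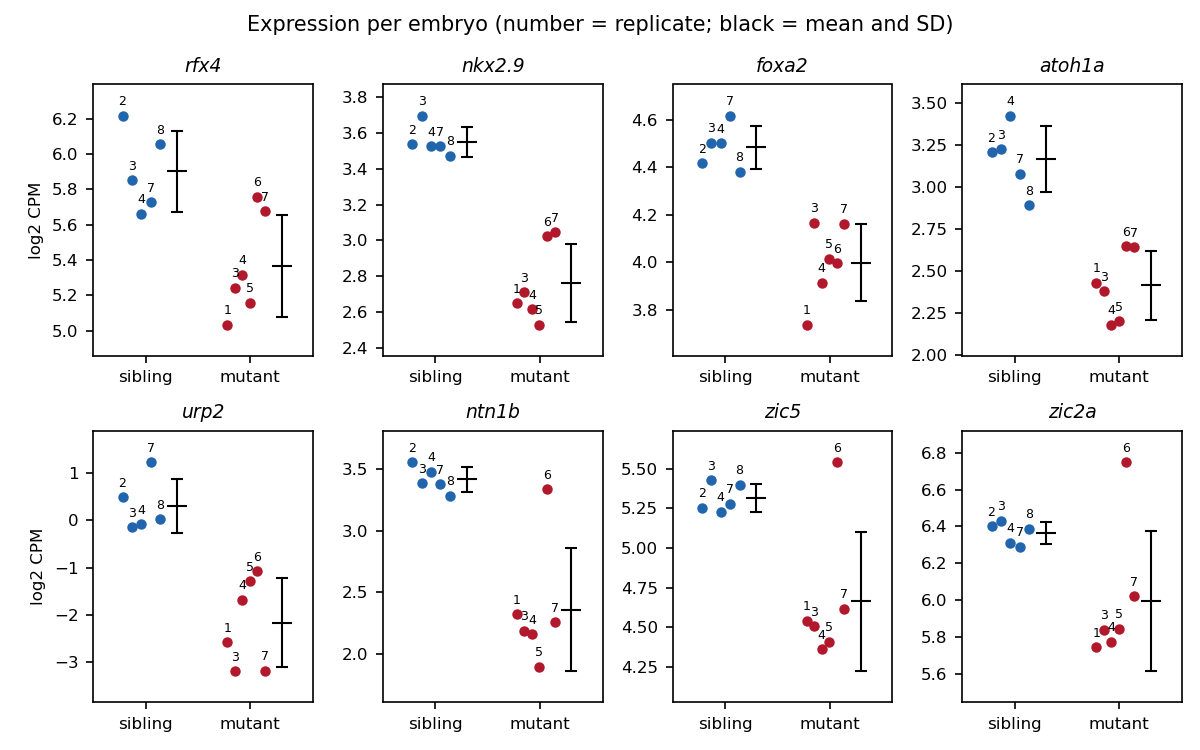
Expression of 8 genes (vertical axis, log2 CPM, one scale per panel) in 5 siblings (blue) and 6 mutants (red), with 1 numbered point per embryo and the group mean and SD in black. The panels of nkx2.9, foxa2, atoh1a and urp2 show genes named for their lack of overlap. Mutant 6 lies within or above the range of the siblings for ntn1b, zic5 and zic2a.

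The floor plate list was lower in mutants by camera at its preset correlation (adjusted p = 4.2e-08). It did not pass with an estimated correlation (0.242), by fry for a shared direction (0.129) or by permuted list means (0.116). By fry for mixed directions, which asks whether members differ either way, it passed (adjusted p = 0.00089). Of its 19 tested members, 14 had lower and 5 higher fitted values, with a median log2 fold change of −0.24. Adjusted over the list alone, 7 members were lower (nkx2.9, foxa2, ntn1b, nkx2.2b, nkx2.2a, shha and spon1b) and 1 was higher (sulf1, a sulfatase of heparan sulfate, 0.20 ± 0.05 SE). DESeq2 over all genes called 4 lower members, nkx2.9, foxa2, ntn1b and nkx2.2b (adjusted p = 0.0499), and edgeR called 0. The mean log2 CPM of the list was 4.41 ± 0.16 in mutants (SD, n = 6) and 4.68 ± 0.07 in siblings (SD, n = 5). Without mutant 6, whose list mean of 4.69 lay among the siblings, the adjusted p with an estimated correlation was 0.0124, with 12 members lower and 2 higher when adjusted over the list alone. Removing a mutant with a sibling-like mean had to widen the difference, so these values are no independent support. The Hedgehog pathway list, which shares nkx2.2a and nkx2.2b with the floor plate list, did not pass by camera (adjusted p = 0.930) but passed by fry for mixed directions (0.0076). Those 2 genes, which lie downstream of Hedgehog signalling, were its only members past 0.05 when adjusted over the list alone, at −0.36 ± 0.09 and −0.40 ± 0.10. Its median was 0.03 although camera gave the direction as down, and that direction turned with upper-quartile or total-count scaling. The list of V3 and cerebrospinal-fluid-contacting neurons did not pass by camera (adjusted p = 0.282) but passed by fry for mixed directions (1.1e-05). Its median was 0.06 and its mean −0.27, and 2 of its 10 members were lower when adjusted over the list alone, urp2 and the transcription factor gene tal2 (−0.39 ± 0.10).

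All 7 zic genes had lower fitted values in mutants. Their median log2 fold change was −0.23, and zic6 (−0.67 ± 0.16 SE) and zic5 (−0.59 ± 0.19) were lower when adjusted over the list alone. DESeq2 over all genes called zic6 (adjusted p = 0.0309), and edgeR called 0 members. The mean log2 CPM of the list was 5.55 ± 0.27 in mutants (SD, n = 6) and 5.89 ± 0.10 in siblings (SD, n = 5). Mutant 6 had the highest value of all 11 embryos, 6.06. Camera gave an adjusted p of 1.0e-06, and the adjusted p was 0.242 with an estimated correlation. Without mutant 6 that value was 0.0124, and 6 of the 7 genes were lower when adjusted over the list alone. Leaving out the highest mutant had to lower the mutant mean. This embryo was also chosen after its effect on the calls was seen, so these values are no independent support. Since the growth protocol names parents with zic2 mutations, the level of zic2a does not tell which mutation the embryos carried. The wider list of roof plate and dorsal neural tube genes was lower by camera (adjusted p = 0.0134, and 0.668 with an estimated correlation), but the shift was small. Its median was −0.05 over 24 members, 16 with lower and 8 with higher fitted values. Only atoh1a passed when adjusted over the list alone, and its paralog atoh1b was at −0.41 ± 0.13 SE. The call was lost without mutant 1, 3 or 5 or sibling 4 (adjusted p = 0.0884, 0.0760, 0.0866 and 0.0571), and without mutant 6, whose list mean of 4.01 was the highest of the 11 embryos, it was 1.3e-07 (0.161 with an estimated correlation), with 7 members lower when adjusted over the list alone. The limit given for the zic list holds for this removal of mutant 6 too. The member with the largest fitted change, rspo1, was higher in mutants (2.82 ± 1.18 SE) and did not pass over the list alone. It was at 43.5 CPM in mutant 6 and at 0.32 to 5.17 CPM in the other embryos, which raised the list mean of mutant 6. That mean was not taken without rspo1. The list of hindbrain and dorsal interneuron genes did not pass by camera (adjusted p = 0.893, median 0.01 with camera's direction down). It passed by fry for mixed directions (adjusted p = 0.026). Its members of lowest p, barhl1b and tlx3b, were at −0.65 ± 0.19 and 0.36 ± 0.12.

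**Figure D2:**
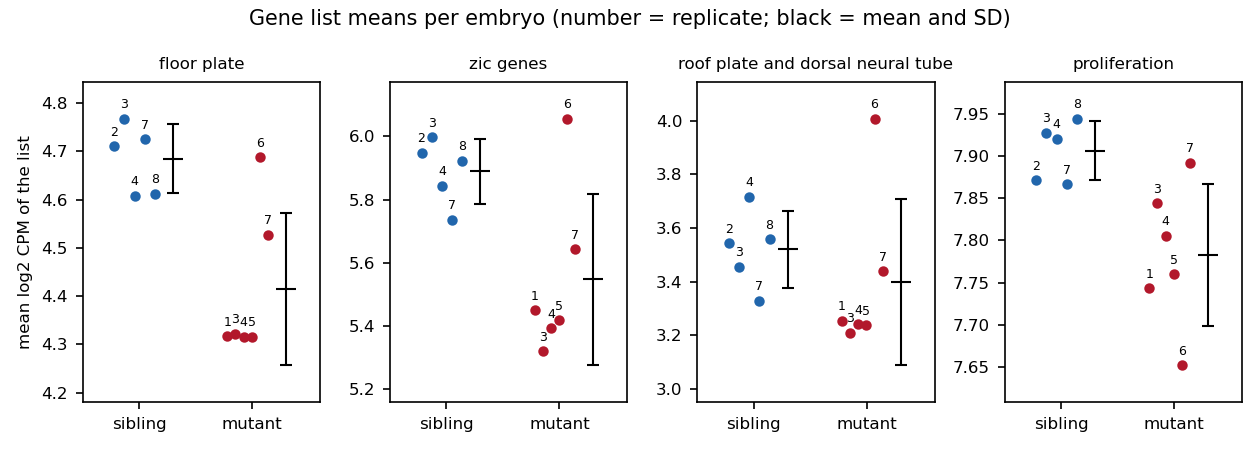
Mean log2 CPM (vertical axis, one scale per panel) of the floor plate, zic, roof plate and proliferation lists in 5 siblings (blue) and 6 mutants (red), with 1 numbered point per embryo and the group mean and SD in black. Mutant 6 lies at 4.69 in the floor plate list and 6.06 in the zic list, against 4.32 to 4.53 and 5.32 to 5.64 in the other mutants, and at 4.01 in the roof plate list.

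The lists of proliferation and neural progenitor genes were slightly lower in mutants by camera at its preset correlation (adjusted p = 4.2e-08 and 1.0e-04), and neither passed with an estimated correlation (0.242 and 0.554). In the proliferation list 22 of 23 members had lower fitted values, with a median of −0.12, and none passed alone. The ribonucleotide reductase genes rrm1 and rrm2 were at −0.31 ± 0.09 SE and −0.29 ± 0.10 SE. The list mean was 7.78 ± 0.08 log2 CPM in mutants (SD, n = 6) and 7.91 ± 0.04 in siblings (SD, n = 5), with mutant 6 the lowest embryo at 7.65. In the neural progenitor list 20 of 28 members had lower fitted values, with a median of −0.08. Adjusted over the list alone, 4 members were lower, the proneural genes ascl1b (−0.47 ± 0.11), ascl1a (−0.31 ± 0.08) and neurog1 (−0.31 ± 0.09) and fabp7a (−0.49 ± 0.11), a radial glia marker, and DESeq2 over all genes called ascl1b and fabp7a. The brain region list was higher without sibling 3 at the preset correlation (adjusted p = 0.0416), where no estimated correlation was run. Over all embryos the neuron list (adjusted p = 0.462) and the brain region list (adjusted p = 0.352) did not pass. Of their members, stmn2b was at 0.33 ± 0.11, tubb5 at −0.21 ± 0.09, mafba at 0.28 ± 0.10 and hoxc6a at 0.24 ± 0.11. The lens and eye list was lower, with 16 of 25 members at lower fitted values and a median of −0.16 (camera adjusted p = 0.0033, and 0.242 with an estimated correlation). The aquaporin gene mipb was at −0.64 ± 0.25 and the retinal ganglion cell gene atoh7 at −1.10 ± 0.44, with 0 members passing alone.

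The notochord and hypochord list and the somite and muscle list were higher by camera at its preset correlation (adjusted p = 7.0e-04 and 0.0037), and neither passed with an estimated correlation (0.242 and 0.668). In the notochord and hypochord list 10 of 12 members had higher fitted values, with a median of 0.14. The notochord collagen gene col8a1a was higher when adjusted over the list alone, and flh, a homeobox gene of the notochord, was at 0.51 ± 0.19 SE. In the somite and muscle list 21 of 34 members had higher and 13 lower fitted values, with a median of 0.04. Its members of lowest p, meox1 and the muscle determination gene myf5, were at 0.37 ± 0.10 and 0.39 ± 0.14, and 0 members passed alone. Its call was lost without mutant 4 or sibling 4 or 8 (adjusted p = 0.126, 0.0713 and 0.0936). The blood and endothelium list (adjusted p = 0.282), the epidermis and hatching gland list (adjusted p = 0.244) and the neural crest and pigment list (adjusted p = 0.925) did not pass. Without mutant 6 the blood list was higher (adjusted p = 0.0077, and 0.549 with an estimated correlation), and without mutant 4 or sibling 3 the epidermis list was lower (0.0249 and 0.0057). The crest list had a median of −0.003 and a mean of 0.003. Of their members, etv2 was at 0.23 ± 0.08, egfl7 at 0.25 ± 0.10, krt8 at −0.19 ± 0.10, agr2 at −0.19 ± 0.12, snai1b at 0.52 ± 0.15 and snai2 at 0.14 ± 0.06.

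RFX factors are known regulators of ciliary genes, and the ciliary lists did not pass over the 11 embryos. Of 33 core ciliogenesis genes, 23 had higher and 10 lower fitted values (median 0.05, camera adjusted p = 0.102), and of 37 motile cilia genes, 18 were higher and 19 lower (median −0.05, mean 0.007, adjusted p = 0.586). The members of lowest p were ift80 (0.20 ± 0.08 SE), ift22 (0.24 ± 0.11), spata18 (−0.39 ± 0.11) and tekt4 (0.42 ± 0.16), and none passed when adjusted over the lists alone. Without mutant 6 the motile cilia list was lower (adjusted p = 0.0151, and 0.471 with an estimated correlation). The core list was higher without mutant 1 or 5 (0.0384 and 0.0276) and with the TPM values (0.0307 to 0.0409), both at the preset correlation only. The Rfx family list, of which 4 members were tested, was lower by camera (adjusted p = 0.0181, and 0.242 with an estimated correlation), a call lost without mutant 4 or sibling 8 (0.0948 and 0.0792). These 4 include rfx4 itself, with the largest change among them (−0.53 ± 0.14), and the list was not tested without it. The member rfx3 was at −0.01 ± 0.10. Adjusted over the list alone, rfx2 and rfx4 were lower and rfx1a was higher (0.28 ± 0.10). Expression of rfx2 was 47.2 ± 4.2 CPM in mutants (SD, n = 6) and 60.9 ± 3.3 CPM in siblings (SD, n = 5). The groups did not overlap, but rfx2 was also named by a rule that asked for this, so the lack of overlap adds no support.

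The list of immediate early and stress genes was higher by camera (adjusted p = 0.0470, and 0.509 with an estimated correlation), with 14 of 21 members at higher fitted values. That call was lost without mutant 3, 5 or 7 or sibling 2, 3, 4 or 8 (adjusted p = 0.0570 to 0.205). Its members fos and gstp1 were at 1.99 ± 0.63 and −0.29 ± 0.10, and 0 members passed alone. The gene cdkn1a, which encodes the cell cycle inhibitor p21, was at 177 CPM in mutant 6 and at 11.9 to 43.1 CPM in the other 10 embryos, and without mutant 6 its log2 fold change was 0.41 ± 0.36 SE. The Wnt list was higher without mutant 5 or sibling 3 at the preset correlation (0.0302 and 0.0452), where no estimated correlation was run. Over all embryos the Wnt target list (adjusted p = 0.193) and the Bmp target list (adjusted p = 0.418) did not pass. Of their members, notum1a was at −0.46 ± 0.22, tcf7 at 0.22 ± 0.10, hey1 at 0.24 ± 0.10 and vent at 0.73 ± 0.34. Without mutant 6 these were −0.71 ± 0.13, 0.19 ± 0.11, 0.30 ± 0.08 and 0.33 ± 0.21, in the same order. In all, 11 of the 23 lists passed with camera at its preset correlation, 4 higher and 7 lower, and 0 passed with an estimated correlation, by fry for a shared direction or by permuted list means. By fry for mixed directions 9 lists passed. They were V3 and cerebrospinal-fluid-contacting neurons (adjusted p = 1.1e-05), floor plate (0.00089), notochord and hypochord (0.0059), Hedgehog pathway (0.0076) and roof plate (0.023). The others were hindbrain and dorsal interneurons (0.026), proliferation (0.041), neural progenitors (0.042) and immediate early and stress (0.042). Without mutant 6 the zic and floor plate lists passed with an estimated correlation and by fry (adjusted p = 0.0026 for each), and 0 lists passed by permuted list means (0.0730 for each of these 2), where at least 4 lists had to reach the smallest possible p, 0.0079, for any to pass. Mutant 6 was left out after its effect was seen, so the passes of these 2 lists are no independent support.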

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

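The tests for a mislabelled embryo, for mixed RNA and for sequencing depth were chosen after the values had been seen. Each group of embryos was searched for an embryo far from the rest, by the gap to its nearest neighbour as a share of the group's range. This gave 26 cases among 202 groups of values, where chance gives about 10.1, and 14 of the 26 were mutant 6. The genes searched include the 24 that were named because edgeR called them without mutant 6, which builds in part of this excess. Outside those 24 genes there were 15 cases among 154 groups, where chance gives about 7.7, and 5 of the 15 were mutant 6. Among genes lower in the other mutants, mutant 6 stood above them at a log2 CPM of 3.28 for bicc2, 3.34 for ntn1b, 4.66 for zic6, 5.54 for zic5, 6.75 for zic2a, 3.87 for shhb, 1.66 for lmx1a, 4.58 for adamts3 and 5.13 for crb1. It also stood above the other mutants for the lens gene mipb (2.38) and the Bmp target vent (2.43), and below them for tuba1b (6.90) and rrm1 (8.85). Its mean log2 CPM was 4.01 for the list of roof plate and dorsal neural tube genes (other mutants 3.21 to 3.44). That mean includes rspo1, at 43.5 CPM in mutant 6 and 0.32 to 5.17 CPM in the other embryos. Mutant 7 stood above the other mutants in the brain region list, at 4.64. Sibling 3 stood apart for nkx2.9 (3.69), meox1 (5.43), mipb (1.27) and the Wnt target list (4.34). Sibling 4 stood apart for fabp7a (7.05), atoh7 (−1.51) and cdkn1a (5.17). Sibling 7 did so for snai1b (2.63), fam167ab (4.45) and the neural crest and pigment list (4.71), and sibling 8 for ift80 (3.80).

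Of the 24 genes called without mutant 6, this embryo lay outside the sibling range on the mutant side for 8, and above or below all siblings on the far side for 7. Chance would give a further sibling 4 on the mutant side for genes not chosen on these siblings. These genes were chosen for a low spread in the other 10 embryos, so 4 may be too low. A sibling labelled as a mutant would lie on the mutant side for few of the 24 genes. The count of 8 lies between what that and a correct label would give, so a mislabelled embryo cannot be told apart from a true mutant here. RNA mixed from a mutant and a sibling in 1 proportion would place every gene at one share of the way between the groups, and mutant 6 lay within the range of the other mutants for 2 genes, within that of the siblings for 9, and at shares from 0.30 for pi15a to 1.74 for zic2a. The best single share of the way to the siblings was 0.89 by the dispersion trend and 0.97 by gene-wise dispersions, so such a mixture would be mostly sibling RNA. By the trend, 4 of the 24 genes lay over 2 SD away, against 0 to 4 for each sibling held out. The mean squared deviation was 2.05 against 0.46 to 1.63. By gene-wise dispersions these values were 8 genes against 0 to 2, and 2.91 against 0.44 to 1.11. Mutant 6 thus had the largest mean squared deviation by both. The genes were chosen for a low spread in the other 10 embryos, which include the siblings held out, so a mixture stays open. Neither explanation by itself gives the 42 higher and 107 lower genes in which mutant 6 stood over 2-fold beyond all 10 other embryos, and a milder or later phenotype was not tested.

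Mutant 7 and sibling 3 shared low levels of lipoprotein and complement transcripts, with apobb.1 at 2352 and 2600 CPM against 6462 to 11217 CPM in the other 9 embryos. Less RNA from the yolk syncytial layer or the liver is a candidate explanation, and these values cannot tell the 2 tissues apart. For 25 of 28 further genes of those tissues, listed before their values were seen, these 2 embryos were the 2 lowest of 11, with a median difference of −0.92 on the log2 scale, as for the transferrin gene tfa (834 and 872 CPM against 1686 to 3375 CPM). Lower sequencing depth is argued against, since sibling 3 ranked 1 of the 11 libraries by total count. The 28 genes also cannot tell less tissue from lower transcription within it. Among them the transcription factor gene hnf4a was at 4.12 CPM in mutant 7 and 3.78 CPM in sibling 3, against 5.11 to 13.4 CPM in the others. The pair holds 1 embryo of each group, and no biological explanation from the design was tested.

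The count of genes past the threshold was set against other splits of the embryos into groups of the same sizes. By edgeR over all 11 embryos the real split gave 0 genes, the highest of the others 2, and all 100 splits gave as many as the real one, which a count of 0 fixes beforehand, so nothing is decided. By DESeq2 the real split gave 43 genes and another gave 58, so 2 of 40 splits gave as many and chance is not excluded. Without mutant 6 the real split gave 24 genes by edgeR and the highest of the others 2, so 1 of 100 splits, the real one, gave as many. This does not exclude chance, since mutant 6 was left out because its removal gave the most calls of the 11 single removals, a choice the other splits did not have.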

How the results depend on the processing

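The removals of mutant 7 with sibling 3, alone and with mutant 6, and the permuted list means were chosen after the data were seen. The same holds for the estimated correlation and fry without mutant 6. The cause of each change below was not tested. The 0 calls of edgeR became 43 by DESeq2 (20 higher, 23 lower), 2 by limma-voom (2 lower), 32 by voom with sample weights (7 higher, 25 lower), 2 at a threshold of 0.1 (2 lower) and 34 without mutant 6, mutant 7 and sibling 3 (8 higher, 26 lower). They ranged from 0 to 24 when single embryos were left out, with 0 to 3 higher and 0 to 21 lower. The count was 0 in all other settings, including without mutant 7 and sibling 3. The rfx4 fold change was lower in mutants throughout, and passed at −0.70 with sample weights and −0.74 without mutant 6, mutant 7 and sibling 3. In each of these 2 fits 1 call lay on the chromosome of rfx4, and it was rfx4. With 0 calls the planned test of calls by chromosome, and its repeat at 0.01, gave nothing to test. DESeq2 gave no list test.

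The replicate numbers 3, 4 and 7 occur in both groups, but same-numbered embryos did not deviate together (correlations −0.31, −0.19 and −0.14), and of the 3 mutants none matched best with its own number. With the replicate block, which rests on those 3 pairs, edgeR called 0 genes (289 at an unadjusted p under 0.05) and 7 lists passed, without proliferation (0.114), neural progenitors (0.473), somite and muscle (0.393), the Rfx family (0.353) and immediate early genes (0.230), and with blood higher (0.00030). Under it the fitted value turned to −0.31 for cdkn1a, and the direction turned for the lists of the Hedgehog pathway (adjusted p = 0.230), hindbrain and dorsal interneurons (0.522) and neural crest (0.514).

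The number of lists past the threshold, 11, was 7 at 0.01, where the roof plate list (0.0134) was lost, and 7 to 12 when single embryos were left out. It was 9 to 11 under the other normalisations, tests, filters and the TPM values, where the Rfx family (0.0589 to 0.167) and immediate early (0.0531 to 0.111) lists were lost in some. Core ciliogenesis passed with all 3 uses of the TPM values (0.0307 to 0.0409, higher). The number of lists was 0 with an estimated correlation (zic and floor plate 0.242, roof plate 0.668), 0 with fry (zic 0.186, floor plate 0.129, roof plate 0.555), 0 with permuted list means (zic 0.141, floor plate 0.116, roof plate 0.714, and neural crest turned at 0.978) and 2 with an estimated correlation without mutant 6 (roof plate 0.161, with neural crest turned at 0.628 and Wnt targets at 0.997). With fry for mixed directions 9 lists passed, and the zic list, at 0.133, did not. Other lists that turned had an adjusted p over 0.05. They were the Hedgehog pathway with upper-quartile factors (0.954), total counts (0.910) and limma-voom (0.921), neurons (0.768) and neural crest (0.755) with sample weights, V3 neurons under the stricter filter (0.702), and core ciliogenesis (0.670), neurons (0.419), neural crest (0.670) and Wnt targets (0.622) without mutant 6, mutant 7 and sibling 3. With single embryos left out, adjusted p ranged from 1.3e-07 to 0.0884 for the roof plate list, 0.393 to 0.999 for the Hedgehog pathway, 0.0302 to 0.984 for Wnt targets, 0.0077 to 0.933 for blood, 0.0416 to 0.823 for brain regions, 0.217 to 0.969 for hindbrain interneurons, 0.0151 to 0.976 for motile cilia, 0.240 to 0.970 for neural crest and 0.103 to 0.984 for neurons, each with a turn of direction except the roof plate list. Depth limits genes such as urp2, with a mean of 12.5 counts per embryo.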

Other observations

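The test of genes near rfx4 was chosen after the values had been seen. Mutant 6 stood apart from all 10 other embryos by more than 2-fold in 42 genes that were higher and 107 that were lower, of 11263 genes with a mean count over 30, whereas no other embryo reached more than 10 higher or 14 lower genes. The genes named here were picked after their values were seen. Among the higher ones, levels of phlda3 were 128 CPM against 7.46 to 22.6 CPM in the other embryos, those of casp8 124 CPM against 9.41 to 21.2 CPM, those of mdm2 416 CPM against 53.1 to 138 CPM, and those of ccng1 3214 CPM against 487 to 1363 CPM. For each of these genes mutant 1, mutant 5 and sibling 4 were the highest of the other embryos, for ccng1 at 1363, 1157 and 1202 CPM. Among the lower ones, the haem synthesis gene alas2 had 301 counts against 1163 to 2712. The embryonic globin gene hbae3 was at 122 CPM against 286 to 565 CPM, the erythropoietin receptor gene epor at 1.79 CPM against 4.43 to 7.67 CPM, drl at 7.77 CPM against 21.7 to 39.2 CPM, and the cotransporter gene slc12a3 at 2.93 CPM against 19.3 to 34.1 CPM.

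The gene rspo1 encodes a secreted enhancer of Wnt signalling and is a member of the roof plate and dorsal neural tube list. It had 727 counts in mutant 6, 93 in mutant 1, 58 in sibling 4 and 41 in mutant 5, and 5 to 21 in the other 7 embryos.

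A few genes had no or almost no counts in 1 or more embryos and clear counts in the rest. The gene rab33ba had 0 counts in mutant 7 and 166 to 214 in the other 10 embryos. The gene lin7b had 2 counts in sibling 7 and 48 to 197 in the others, and si:dkey-102c8.3 had 0 counts in mutants 3, 6 and 7 and 50 to 295 in the others.

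Mutants from an incross share the haplotype around the mutated gene, so linked variants could give differences near rfx4. Of the 50 tested neighbours on each side of rfx4, in the gene order of GRCz12tu, 1 of 100 had an unadjusted p under 0.05, against 6.91% of the other tested genes with a place in that assembly (Fisher's exact p = 0.0148). On the whole chromosome 0 of 429 genes other than rfx4 were DESeq2 calls, against 43 of 11730 elsewhere (Fisher's exact p = 0.406), too few to decide. At an unadjusted p under 0.05 there were 18 of 429, against 816 of 11730 elsewhere (Fisher's exact p = 0.0249). Both shares at that unadjusted p were thus lower than elsewhere, and the cause of this deficit was not tested. The count among the neighbours argues against an excess of differences near rfx4.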
